A study of Mus musculus with 8 samples.

How the data were processed

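RNA from bone-marrow-derived macrophages of Tpl2 wild-type and Tpl2-deficient mice, left unstimulated or treated with LPS from Escherichia coli at 1 μg/mL, was hybridised to 8 Affymetrix mouse arrays, 2 per group of genotype and treatment. Per the labels, bone marrow cells were cultured with macrophage colony-stimulating factor and adherent cells were harvested, total RNA was purified on columns, and it was labelled with biotin. The treatment notes mention several time points and inhibitors but do not assign a time to these arrays. The deposited values are on the log2 scale: GCOS and RMA are named in the submitters' processing notes, with no versions, and the chip definition file is not given in the sources used here. That the values are log2 was checked on the file itself, where all 45101 probe sets lie in the range of log2 RMA values in every array. No further normalization was applied, and no value was filtered out for being low. The choice to read changes from or to a level under the array median as lower bounds was made after the values were seen.

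Probe sets were paired with gene symbols through the array's annotation table. Exactly 1 symbol was listed for 34958 probe sets, of which 34945 were used after control probe sets were set aside; 932 list several symbols, 9211 list none, and 64 are controls. A gene was represented by its probe set with the highest mean over the 8 arrays, which gave 18193 genes, 9010 of them with several probe sets. Symbols of 34741 probe sets matched the RefSeq gene table of assembly GRCm38.p6, and 0 symbols needed updating. That table was used for names and for which genes neighbour each other, and no coordinates are given because the files name no genome build.

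Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) on all 8 arrays, with a mean for each of the 4 groups and no batch or replicate term. This leaves 4 residual degrees of freedom, and the fit added 6.87 prior degrees of freedom. The comparisons were LPS against unstimulated in each genotype, Tpl2-deficient against wild type without and with LPS, and the difference of the LPS responses, 5 in all. A gene passed at a Benjamini-Hochberg adjusted p under 0.05 over all genes. Shifts of 31 of 32 gene lists (at least 5 measured members; the sex-linked list with 4 was not tested) were tested with limma's camera at its preset correlation of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation and fry, a test of each list alone, were run beside it. With an estimated correlation, camera passed 0 of the 31 lists for LPS in either genotype. This included lists of which every member rose, so a call lost with it does not show that a list did not shift. Of 623 list entries 561 were measured. The lists cover chemokine ligands, chemokine receptors, inflammatory cytokines, anti-inflammatory and feedback genes, ERK-responsive genes, interferon-stimulated genes, NF-kB genes, antimicrobial genes, adhesion and migration genes, alternative activation, cell cycle, cholesterol synthesis, LXR targets, glycolysis and HIF-1 targets, MHC class I and II, the toll-like receptor pathway, NRF2 targets, the Tpl2 pathway and neighbours of Map3k8. They also cover markers of macrophages, neutrophils, dendritic cells, T and NK cells, B cells, erythroid cells, mast cells, stromal cells, osteoclasts and progenitors, sex-linked genes and reference genes.

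The samples' groups, the test, the gene lists, the rule for named genes and the alternatives listed below, save the last pair, were fixed before the data were examined. The rule takes, per comparison, the 8 largest rises and the 8 largest falls among genes past the threshold whose groups do not overlap (without that condition for the interaction), up to 4 members past the threshold per list (8 for the chemokine lists), and a fixed set of genes whatever their p, 23 of which were measured. Further list members named in the text were chosen after their values were seen. Predicted genes and cDNA clones are left unnamed.

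The alternatives were the mean of all probe sets of a gene, each probe set on its own, leaving out _x_at and _s_at probe sets (which may cross-hybridise), quantile normalization repeated, centring each array on its median, only genes above the median level, a mean-variance trend, a robust variance prior, array weights, only the 4 arrays compared, a 2-fold minimum, a replicate block and leaving out each array in turn. Centring on the hybridisation spike-ins and a crossed pairing were added after seeing the data. The method was tested on simulated data with 200 of 18193 genes changed: for the unstimulated genotype comparison it recovered 89.6% of genes changed 1.5-fold, 100% at 2-fold and 98.5% at 4-fold, with 13 false among 205 calls, and for the LPS-treated comparison 77.6%, 100% and 100%, with 10 false among 195. The simulated values were independent normal draws with the same spread of a gene in all groups. The wider spread of the LPS-treated Tpl2-deficient arrays was not simulated, so these rates may not hold for the real arrays.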

Results

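Gene expression was measured on 8 Affymetrix arrays of mouse macrophages grown from bone marrow in macrophage colony-stimulating factor. Tpl2 is a kinase, encoded by Map3k8, that activates MEK and ERK after toll-like receptor signals. The arrays form 4 groups of 2: wild-type and Tpl2-deficient macrophages, each left unstimulated or treated with LPS, a bacterial toll-like receptor 4 ligand, at 1 μg/mL. The labels do not give the time of LPS treatment for these arrays. The series title names chemokine and chemokine receptor expression and macrophage migration, so those gene lists lead each comparison. Values are log2 RMA intensities for 18193 genes, and arrays have no read depth, so the number of arrays limits the precision. The labels call the 2 arrays of a group biological replicates without saying whether they come from separate animals, and the p-values measure only the spread between these samples. Arrays of the same group correlated across probe sets at r = 0.997 in 3 groups and 0.994 in the LPS-treated Tpl2-deficient group, whose median SD between its 2 arrays was 0.129 against 0.0649 to 0.0662 in the others. Differences below are log2 changes ± standard error from a limma fit to all 8 arrays, with Benjamini-Hochberg adjusted p-values. The fit assumes the same spread of a gene in all groups. Standard errors and p-values of comparisons with the LPS-treated Tpl2-deficient group may therefore be too small. The files hold no detection calls, so no signal was shown to be above background. Where the lower of the group means lies under the median of its arrays (6.48 to 6.53), the change is read as a lower bound and its fold is written with "at least". In the 4 comparisons of groups, this holds for 2319 of 9499, 1338 of 7596, 20 of 91 and 329 of 2500 calls, in the order of the report. Among the log2 changes below it holds for the LPS rises of Il6, Ptgs2, Cxcl9, Cxcl3, Ccr3, Il1a, Il10, Il12b, Lhx2 and, in Tpl2-deficient cells, Ccl7, Cxcl11 and Zeb1, for the falls of Cnr2 and Ccr1, and for the genotype differences of Uchl1 and Fzd8 at rest and of Ccr1, Ccr3, Cd300lb and Olr1 under LPS. A difference of LPS responses that rests on such a level is no bound. For 1413, 699, 11 and 147 of the calls, in the same order, both group means lie under the medians. Expression in either group was then not shown. Ccr3 in wild-type cells and between the genotypes under LPS, and Fzd8 at rest, are among these.

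Map3k8, the targeted gene, was lower in both Tpl2-deficient groups. Its mean level in unstimulated cells was 9.27 ± 0.01 in wild type and 8.28 ± 0.06 in Tpl2-deficient macrophages (SD, n = 2), and with LPS it was 10.96 ± 0.07 and 9.96 ± 0.19. It was 2.00-fold lower than in wild type both without LPS (adjusted p = 0.0024) and with LPS (adjusted p = 0.000125), with a standard error of 0.11 on the log2 scale. LPS raised the Map3k8 signal 3.21-fold in both genotypes. A single probe set measures Map3k8, and the labels do not say where the deletion lies relative to it, so the signal left in the deficient cells cannot be read as remaining Tpl2.

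The first comparison asks what LPS does in wild-type macrophages. Il6, a pro-inflammatory cytokine, had the largest measured rise, from 3.70 to 13.65 (9.95 ± 0.10, at least 987-fold). The endothelial lipase Lipg rose at least 363-fold, Ptgs2, the inducible cyclooxygenase, at least 355-fold, and the T cell chemoattractant Cxcl9 at least 349-fold; these have no order, since their unstimulated levels are under the array medians. The chemokine receptor Cxcr4 had the largest measured fall, from 12.90 ± 0.01 to 6.77 ± 0.05 (SD, n = 2; 69.9-fold). Among the next largest falls were the stress-responsive Sesn1 (-5.29 ± 0.13), the cannabinoid receptor Cnr2 (-4.69 ± 0.13) and the iron exporter Slc40a1 (-4.47 ± 0.13). In all, 3872 genes rose and 5627 fell (adjusted p under 0.05, limma), of which 994 and 2116 changed at least 2-fold.

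Of the 34 chemokine ligands measured, LPS raised 22 and lowered 2 in wild-type cells, and 10 did not pass (22 and 2 adjusted over the list alone). The neutrophil attractant Cxcl3 rose by 6.90 ± 0.13, the monocyte attractants Ccl7 and Ccl2 by 5.79 ± 0.11 and 5.65 ± 0.15, and Ccl3 by 3.73 ± 0.09. The list shifted upward (camera, adjusted p = 5.86e-10, but adjusted p = 0.189 with an estimated correlation). Of 22 chemokine receptors, 12 rose and 3 fell (13 and 3 adjusted over the list alone). Ccrl2, an atypical receptor that binds chemerin, rose by 3.94 ± 0.10, Ccr3 by 1.73 ± 0.15 and Ccr1, a receptor for Ccl3, Ccl5 and Ccl7, by 1.15 ± 0.14, while Cxcr3 fell by 1.59 and the fractalkine receptor Cx3cr1 by 1.03. The receptor list's median was 0.39 (camera, adjusted p = 0.0216, but adjusted p = 0.189 with an estimated correlation), and this call was also lost with the mean of all probe sets and among genes above the median level.

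All 34 interferon-stimulated genes and all 18 NF-kB feedback and target genes rose in wild-type cells (the same numbers adjusted over the list alone), with medians of 3.88 and 3.01. Their camera adjusted p-values were 2.1e-27 and 1.32e-15, and both were 0.189 with an estimated correlation. With an estimated correlation camera passed 0 of 31 lists here, although every member of these lists rose. Losing that test therefore says little against a shift. Of 22 inflammatory cytokines, 21 rose and 0 fell, including Il1b (6.93 ± 0.11) and Il1a (5.95 ± 0.13; camera adjusted p = 8.47e-14, adjusted p = 0.11 with an estimated correlation). Of 18 anti-inflammatory and feedback genes, 15 rose and 2 fell, with Il10, an anti-inflammatory cytokine, up by 5.51 ± 0.10 (adjusted p = 7.8e-08, but adjusted p = 0.189 with an estimated correlation). Of 20 antimicrobial and effector genes, 17 rose and 1 fell, among them Acod1, the itaconate-producing enzyme (5.03 ± 0.13; adjusted p = 2.9e-10, but adjusted p = 0.189 with an estimated correlation). Of 12 MHC class I genes, 9 rose and 0 fell (adjusted p = 1.35e-05, but adjusted p = 0.189 with an estimated correlation). Of 28 ERK-responsive genes, 13 rose and 4 fell, with a median of 0.17 that becomes -0.00 when arrays are centred on the spike-ins (adjusted p = 0.0237, but adjusted p = 0.192 with an estimated correlation). Of 35 cell cycle genes, 2 rose and 23 fell (2 and 25 adjusted over the list alone), such as the replication helicase subunit Mcm7, which fell 7.71-fold. That list's camera adjusted p was 0.00798, but its adjusted p = 0.685 with an estimated correlation, and the call was lost among genes above the median level.

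Markers of other cell types were read in the same cells. Of 16 macrophage markers, 4 rose and 6 fell with LPS in wild type; the transcription factor Cebpa fell 21.4-fold and the scavenger receptor Msr1 rose 3.57-fold. Of 13 neutrophil and granulocyte precursor markers, 7 rose and 1 fell, with the iron-binding Lcn2 up at least 57.6-fold (adjusted p = 0.0237, but adjusted p = 0.278 with an estimated correlation, and not past without _x_at and _s_at probe sets). The 3' to 5' signal ratio of Actb, a sign of RNA integrity, was 0.74 ± 0.10 (log2, SD, n = 2) in unstimulated and 0.51 ± 0.06 in LPS-treated wild-type cells, and that of Gapdh was 0.03 ± 0.09 and -0.08 ± 0.01. Falls made up 59.2% of the calls and 77.2% when arrays were centred on the hybridisation spike-ins, whose mean signal was 0.17 higher in the LPS-treated wild-type arrays.

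**Figure D1:**
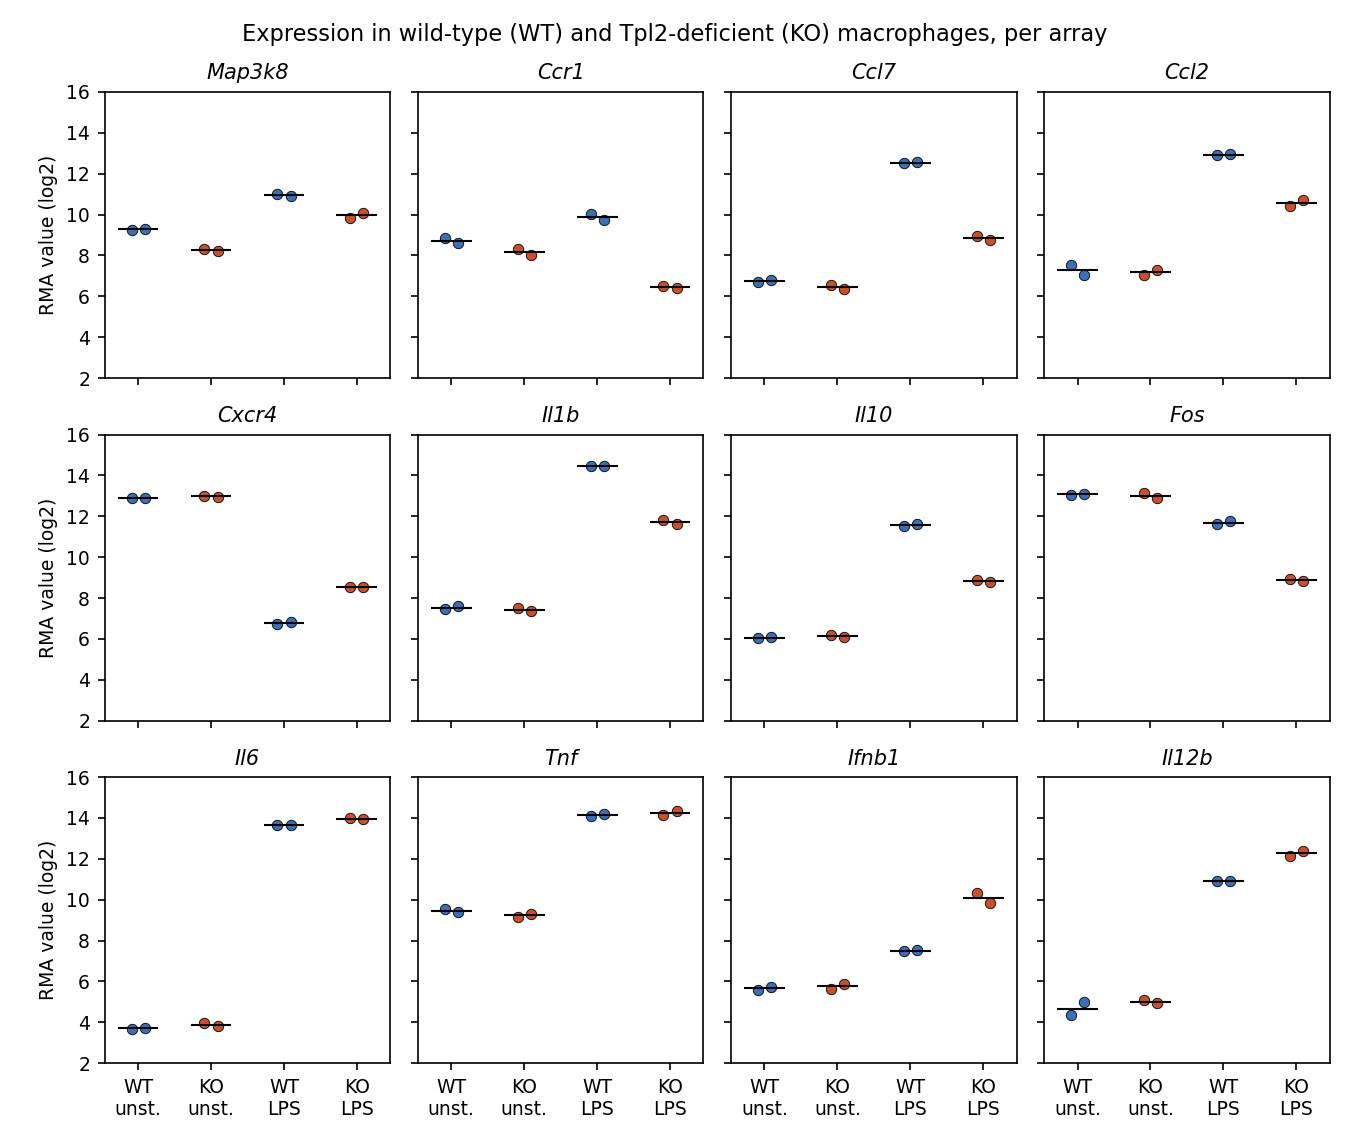
Log2 RMA value of 12 genes in each of the 8 arrays; dots are arrays and lines are the means of the 2 arrays of a group, with WT for wild type, KO for Tpl2-deficient and unst. for unstimulated. With LPS, Ccr1, Ccl7, Ccl2, Il1b, Il10 and Fos lie lower in Tpl2-deficient cells (Ccl7 8.85 against 12.54), Cxcr4, Ifnb1 and Il12b lie higher (Ifnb1 10.08 against 7.51), and Il6 and Tnf do not pass the test. Il6 and Tnf lie high in the arrays with LPS, where a difference could be missed.

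The next comparison asks what LPS does without Tpl2. LPS raised 2903 genes and lowered 4693 in Tpl2-deficient macrophages, 1081 and 1550 of them at least 2-fold. Il6 (10.09 ± 0.10), Ptgs2 (8.36 ± 0.17) and Cxcl9 (8.28 ± 0.13) were among the largest measured rises as in wild type. The interferon-inducible chemokine Cxcl11 (7.79 ± 0.14) and the transcription factor Lhx2 (7.31 ± 0.15) were among them too. These rises are lower bounds and have no order, since their unstimulated levels are under the array medians. The receptor-like gene Cd300lb had the largest measured fall, at least 204-fold, and Cebpa fell 40.1-fold. Of the chemokine ligands, 21 rose and 1 fell (the same adjusted over the list alone; camera adjusted p = 1.01e-11, but adjusted p = 0.164 with an estimated correlation). Of the receptors, 4 rose and 5 fell, and Ccr1 fell by 1.73 where it had risen in wild type. The receptor median was 0.04 (-0.23 with spike-in centring; camera adjusted p = 0.801).

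All 34 interferon-stimulated genes and all 18 NF-kB genes rose in Tpl2-deficient cells too, with medians of 3.70 and 3.20 (camera adjusted p = 3.46e-31 and 2.29e-18, but adjusted p = 0.204 and 0.164 with an estimated correlation). Of the inflammatory cytokines 15 rose and 1 fell, with Tnf up by 4.99 ± 0.11 and Il12b by 7.25 ± 0.18 (adjusted p = 1.01e-11, but adjusted p = 0.152 with an estimated correlation). Of the ERK-responsive genes 4 rose and 14 fell: the AP-1 subunit Fos fell 17.4-fold, the ERK phosphatase Dusp6 at least 21.3-fold and the transcription factor Egr1 3.94-fold, while Dusp2 rose by 4.71 ± 0.11. This list shifted downward (adjusted p = 0.0175, but adjusted p = 0.204 with an estimated correlation, and not past among genes above the median level). Of 12 MHC class II genes, 6 rose and 0 fell, and Ciita, the master regulator of that class, rose by 1.34 ± 0.15 (adjusted p = 0.0138, but adjusted p = 0.248 with an estimated correlation, and not past among genes above the median level). Macrophage markers fell in 9 cases and rose in 4 (camera adjusted p = 0.255). Falls made up 61.8% of the calls and 81.7% with spike-in centring, the spike-in mean being 0.27 higher with LPS, and the Actb 3' to 5' ratio was 0.88 ± 0.03 without and 0.65 ± 0.05 with LPS (Gapdh 0.07 ± 0.01 and 0.08 ± 0.03).

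Across genes, the LPS responses of the genotypes correlated at r = 0.902 (Spearman's rho = 0.807, covariance 0.730); genes are not independent replicates. Of 6415 genes past the test in both genotypes, 6294 moved the same way, where independent calls would give 2069. The median ratio of the Tpl2-deficient to the wild-type change was 0.725 among genes called in wild type and 0.929 among genes called in Tpl2-deficient cells; choosing genes in 1 genotype biases its ratio, so both are given. Among called genes that also changed at least 2-fold in the genotype used for the choice, the ratios were 0.841 and 0.994.

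**Figure D2:**
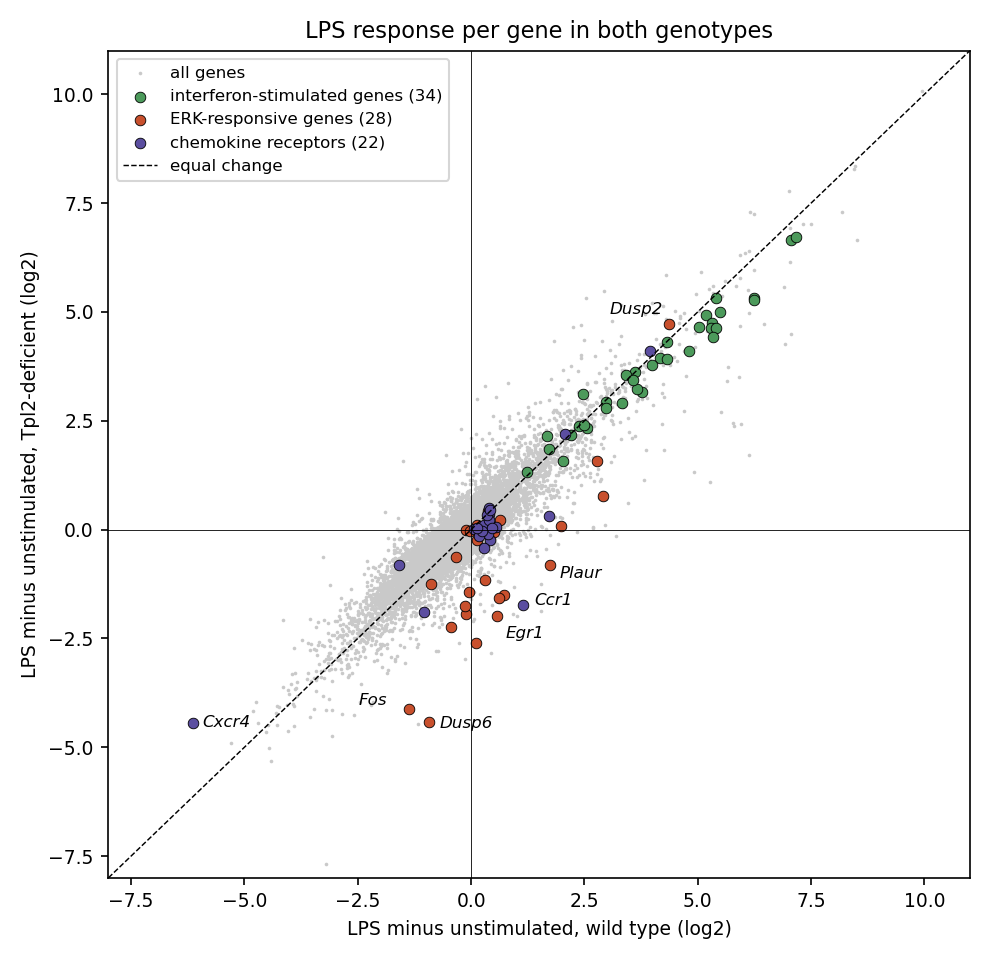
Log2 change with LPS in wild-type (horizontal axis) and Tpl2-deficient (vertical axis) macrophages, 1 point per gene (n = 2 arrays per group), with 3 gene lists coloured and equal change dashed. Interferon-stimulated genes lie near the dashed line (medians 3.88 and 3.70), while Dusp6, Fos, Plaur, Egr1 and Ccr1 lie below it and Cxcr4 above it.

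The comparison of unstimulated macrophages asks what Tpl2 deficiency changes at rest. Few genes passed: 28 were higher and 63 lower in Tpl2-deficient cells, 10 and 16 of them at least 2-fold. Of 18193 genes, 2445 had an unadjusted p under 0.05 (limma), more than the share of 0.05 that no difference would give. Array weights gave more calls (counts further below), so smaller differences at rest may have been missed. The ectoenzyme Enpp4 was the highest, at 9.61 ± 0.14 against 6.67 ± 0.01 in wild type (SD, n = 2; 2.94 ± 0.11, adjusted p = 6e-07). Pik3ap1, an adaptor for PI3 kinase, was higher by 2.11 ± 0.20 and Treml1 by 1.83 ± 0.18, whereas the podoplanin gene Pdpn was 2.40-fold lower, Galnt9 at least 2.52-fold and Bdh1 2.50-fold. The neutrophil attractant Cxcl2 was the only chemokine ligand of 34 to pass, at 8.19 against 9.22 in wild type (-1.03 ± 0.10, adjusted p = 0.0012), and none of the 22 receptors passed (1 higher and 1 lower ligand, and 0 receptors, adjusted over the list alone). Erdr1 (2.22 ± 0.32) and Uchl1 (-2.73 ± 0.42) also passed, but their calls were lost without wild-type unstimulated replicate 2, and the 2 Tpl2-deficient arrays of Uchl1 were far apart (SD 1.19). Probe sets of the related Cxcl1 disagreed. The one used, of the kind that may cross-hybridise, gave 0.31 ± 0.13 and did not pass. Another gave -1.72 and passed when _x_at and _s_at probe sets were left out. That Cxcl2 alone passed therefore holds for the probe sets used only.

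Of 34 interferon-stimulated genes, 3 were higher in unstimulated Tpl2-deficient cells and 0 lower (12 and 0 adjusted over the list alone). Gbp2, an interferon-induced GTPase, was higher by 0.80 ± 0.10, Cmpk2 by 0.88 ± 0.14 and Oasl1 by 0.86 ± 0.14, and each call was lost when wild-type unstimulated replicate 2 or either Tpl2-deficient unstimulated array was left out. The list median was 0.27 (camera adjusted p = 3.42e-09, but adjusted p = 0.704 with an estimated correlation). The medians were -0.37 for 35 cell cycle genes (adjusted p = 2.47e-06), -0.15 for 20 cholesterol synthesis genes (0.00604), -0.12 for 18 anti-inflammatory genes (0.0281) and -0.11 for 22 glycolysis and HIF-1 target genes (0.0454). No member of these 4 lists passed on its own (3 glycolysis genes and 1 anti-inflammatory gene were lower adjusted over the list alone), each list had adjusted p = 0.704 with an estimated correlation, and with spike-in centring the medians of the anti-inflammatory and glycolysis lists turned to 0.02 and 0.03, while those of cholesterol synthesis and cell cycle shrank to -0.01 and -0.23. Among ERK-responsive genes Egr1 was higher (0.81 ± 0.12) and Egr2 lower (-0.64 ± 0.11), and 26 did not pass; both calls were lost without wild-type unstimulated replicate 1 or either Tpl2-deficient unstimulated array. No member of the 10 cell-type marker lists passed, the macrophage median being 0.05; the stromal list shifted downward without Tpl2-deficient unstimulated replicate 1 and upward without replicate 2, but not with both. The Actb 3' to 5' ratio was 0.88 ± 0.03 in Tpl2-deficient and 0.74 ± 0.10 in wild-type unstimulated arrays, and that of Gapdh 0.07 ± 0.01 and 0.03 ± 0.09. Leaving out 1 array left 36 or 23 calls without wild-type unstimulated replicate 1 or 2, and 40 or 29 without Tpl2-deficient unstimulated replicate 1 or 2. Lower genes made up 69.2% of the calls, 33.0% with spike-in centring (the Tpl2-deficient minus wild-type difference of the spike-in mean was -0.14) and 55.7% with quantile normalization repeated, so the balance of higher and lower genes depends on the scaling.

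The comparison of LPS-treated macrophages asks which genes depend on Tpl2 under stimulation, the setting the series title addresses. In Tpl2-deficient cells Ccl7 was 12.9-fold lower (8.85 ± 0.16 against 12.54 ± 0.05, SD, n = 2), Ccl2 5.11-fold lower (10.58 ± 0.20 against 12.94 ± 0.06) and Ccr1 at least 10.7-fold lower (6.46 ± 0.09 against 9.88 ± 0.23). Cxcr4, the receptor of Cxcl12, was 3.40-fold higher, and Ifnb1, which encodes interferon beta, 5.95-fold higher. In all, 1457 genes were higher and 1043 lower, 190 and 272 of them at least 2-fold. Among the genes with the largest differences were Cd300lb (-4.43 ± 0.18), the niacin receptor Hcar2 (-4.08 ± 0.10), the oxidised LDL receptor Olr1 (-3.61 ± 0.14) and the plasminogen activator Plat (3.25 ± 0.16).

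Of the 34 chemokine ligands, 4 were higher, 6 were lower and 24 did not pass (4 and 7 adjusted over the list alone). Ccl7 (-3.69 ± 0.11, adjusted p = 2.19e-08), Ccl2 (-2.35 ± 0.15, adjusted p = 2.32e-06), Cxcl3 (-1.58 ± 0.13) and Cxcl2 (-1.17 ± 0.10) were the most reduced. Cxcl11 was higher by 0.69 ± 0.14 and Ccl22, a ligand of Ccr4, by 0.56 ± 0.12, although both calls were lost without wild-type LPS replicate 1. Other ligands with large LPS responses did not pass: Ccl3 differed by -0.05 ± 0.09, Ccl4 by -0.35 ± 0.11, Ccl5 by 0.10 ± 0.22 and Cxcl10 by -0.14 ± 0.18. With LPS these ligands lay near the top of the arrays in both genotypes. Wild-type and Tpl2-deficient means were 14.73 and 14.67 for Ccl3 and 14.71 and 14.36 for Ccl4. They were 14.67 and 14.77 for Ccl5 and 14.91 and 14.77 for Cxcl10. A difference could be missed at such levels, so independence of Tpl2 was not shown for these ligands. The list's median was 0.00 and its mean -0.22 (camera adjusted p = 0.187), and fry, which tests the list alone, gave adjusted p = 0.0456. Of 22 receptors, 2 were higher, 5 lower and 15 did not pass (2 and 6 adjusted over the list alone; camera adjusted p = 0.134). Ccr1 differed by -3.42 ± 0.14 (adjusted p = 9.0e-08), Ccr3 by -1.41 ± 0.15 and Cxcr4 by 1.77 ± 0.10 (adjusted p = 6.05e-07). The means of Ccr3 (4.93 in Tpl2-deficient and 6.34 in wild-type cells) lay under the array medians in both genotypes. The same held for the lower receptors Ccr1l1 and Cxcr6, so expression of these receptors under LPS was not shown. Ccr2, the main receptor of Ccl2, differed by -0.38 ± 0.12 and did not pass (adjusted p = 0.0717).

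**Figure D3:**
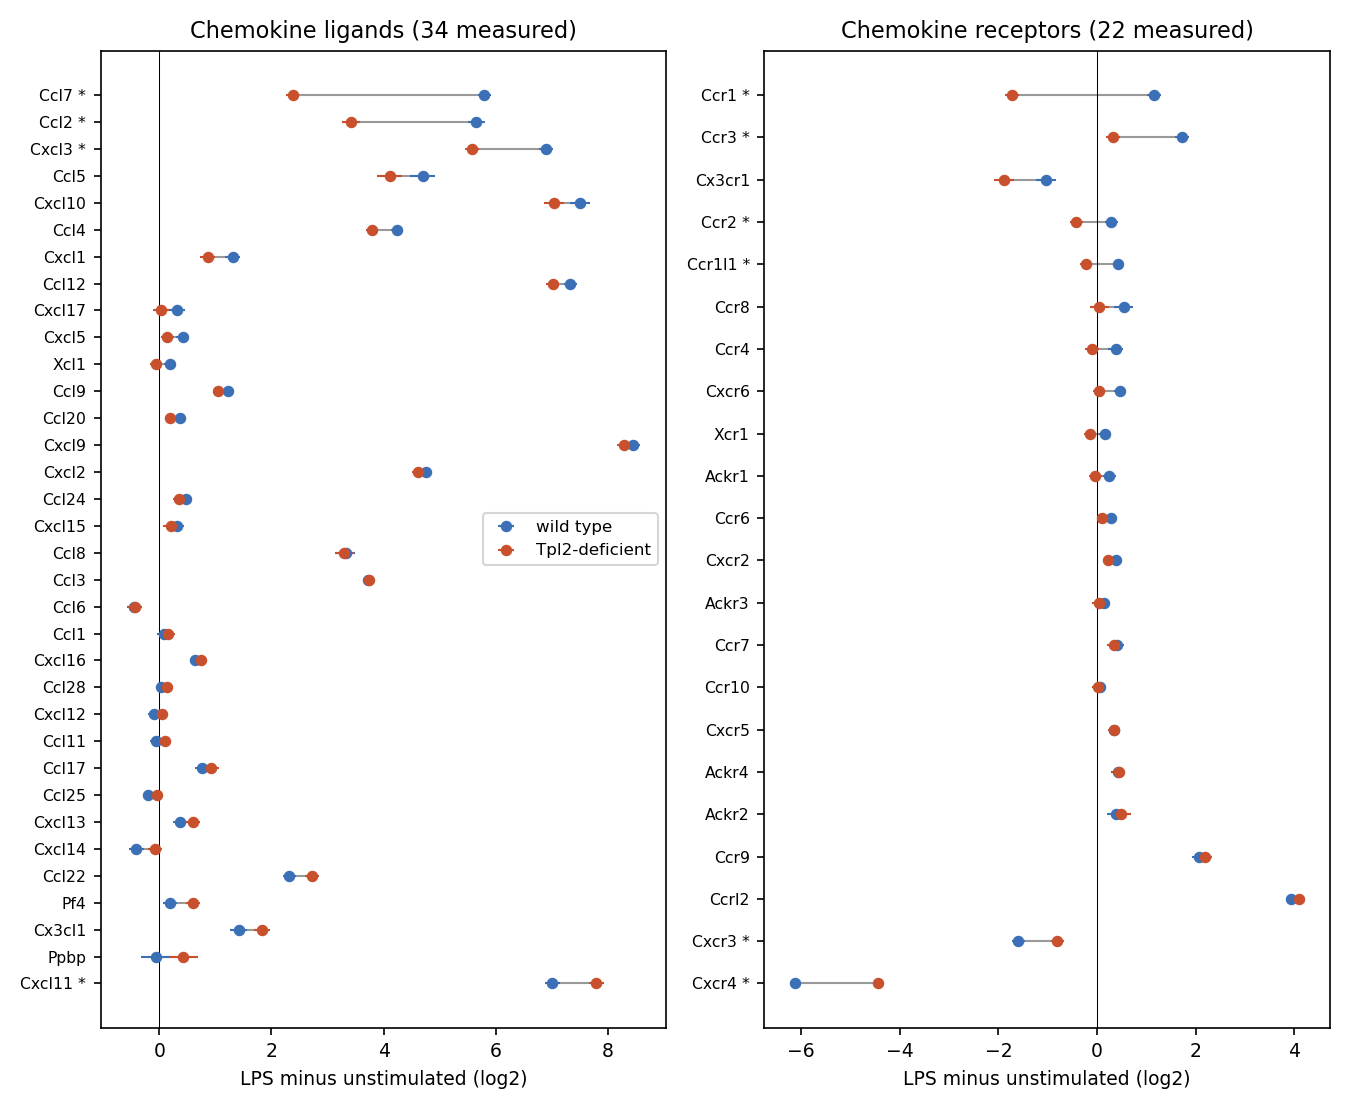
Log2 change with LPS (horizontal axis, ± standard error, n = 2 arrays per group) of each measured chemokine ligand and receptor in wild-type and Tpl2-deficient macrophages, ordered by the difference between the genotypes. Asterisks mark a difference of LPS responses with adjusted p under 0.05, which holds for 4 ligands (Ccl7, Ccl2, Cxcl3, Cxcl11) and 6 receptors (Ccr1, Ccr3, Ccr2, Ccr1l1, Cxcr3, Cxcr4). With LPS, the levels of Ccr3 and Ccr1l1 lie under the array medians in both genotypes. Cxcl1 passed as well when _x_at and _s_at probe sets were left out. Ccr2 passed with the probe set used, while its other probe sets did not pass.

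Of 28 ERK-responsive genes, 18 were lower and 0 higher in LPS-treated Tpl2-deficient cells (20 and 0 adjusted over the list alone). Plaur, the urokinase receptor, was 8.82-fold lower, Fos 7.02-fold, Phlda1 6.91-fold and Ier2 5.71-fold. The list's median was -1.32, and it alone passed camera both with the preset correlation (adjusted p = 3.49e-22) and with an estimated one (adjusted p = 0.0151 with an estimated correlation). Dusp2, which also rose strongly with LPS, differed by 0.16 and did not pass.

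Inflammatory cytokines moved both ways, 6 higher and 7 lower of 22 (9 and 9 adjusted over the list alone; camera adjusted p = 0.453). Il1a was 12.4-fold lower, Il1b 6.78-fold lower (11.71 ± 0.15 against 14.47 ± 0.01, SD, n = 2) and the granulocyte growth factor Csf3 5.55-fold lower. Ifnb1 was higher by 2.57 ± 0.16, and Il12b, a subunit of interleukin-12 and interleukin-23, by 1.36 ± 0.18. Tnf (0.08 ± 0.11) and Il6 (0.31 ± 0.10) did not pass. With LPS their wild-type and Tpl2-deficient means were high in the arrays, 14.15 and 14.23 for Tnf and 13.65 and 13.96 for Il6. A difference could be missed at such levels, so independence of Tpl2 was not shown for them. Of 18 anti-inflammatory and feedback genes, 10 were lower and 2 higher (12 and 2 adjusted over the list alone), with Il10 6.63-fold lower and the mRNA-destabilising Zfp36 2.94-fold lower (camera adjusted p = 4.15e-09, but adjusted p = 0.321 with an estimated correlation). Of 34 interferon-stimulated genes only Irf1 differed (0.73 ± 0.11), and 33 did not pass although Ifnb1 was higher. The median of that list was -0.02, or 0.02 with spike-in centring. Of 18 NF-kB genes, 4 were higher and 2 lower (median 0.04, camera adjusted p = 0.808).

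Of 32 adhesion and migration genes, 13 were lower and 2 higher (14 and 2 adjusted over the list alone). Besides Plaur, the collagenase Mmp13 was 3.41-fold lower, the complement receptor C5ar1 2.11-fold and the protease Adam8 1.99-fold (camera adjusted p = 4.34e-07, but adjusted p = 0.321 with an estimated correlation). Of 20 antimicrobial and effector genes, 7 were lower and 1 higher (10 and 2 adjusted over the list alone), with the protease inhibitor Serpinb2 9.59-fold and the scavenger receptor Marco 6.16-fold lower (adjusted p = 5.07e-05, but adjusted p = 0.321 with an estimated correlation). Of 25 toll-like receptor pathway genes, 7 were lower and 1 higher (8 and 2 adjusted over the list alone), with Tlr4, the LPS receptor, 2.68-fold and Tlr13 2.63-fold lower (adjusted p = 0.000938, but adjusted p = 0.62 with an estimated correlation).

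Of 16 macrophage markers, 5 were lower and 2 higher (6 and 2 adjusted over the list alone). Msr1 was 2.28-fold lower, the Fc receptor Fcgr3 1.78-fold lower and Mertk 1.99-fold higher (list median -0.12, camera adjusted p = 0.00797, but adjusted p = 0.321 with an estimated correlation). Of 13 neutrophil markers 2 were lower, and among the other 8 marker lists the calls per list ranged from 0 to 5. The Actb 3' to 5' ratio was 0.65 ± 0.05 in Tpl2-deficient and 0.51 ± 0.06 in wild-type LPS arrays, and that of Gapdh was 0.08 ± 0.03 and -0.08 ± 0.01 (SD, n = 2). Without wild-type LPS replicate 1 or 2 the calls fell from 2500 to 1387 or 1356, and 1348 and 1320 of those were among the original calls with the same sign.

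**Figure D4:**
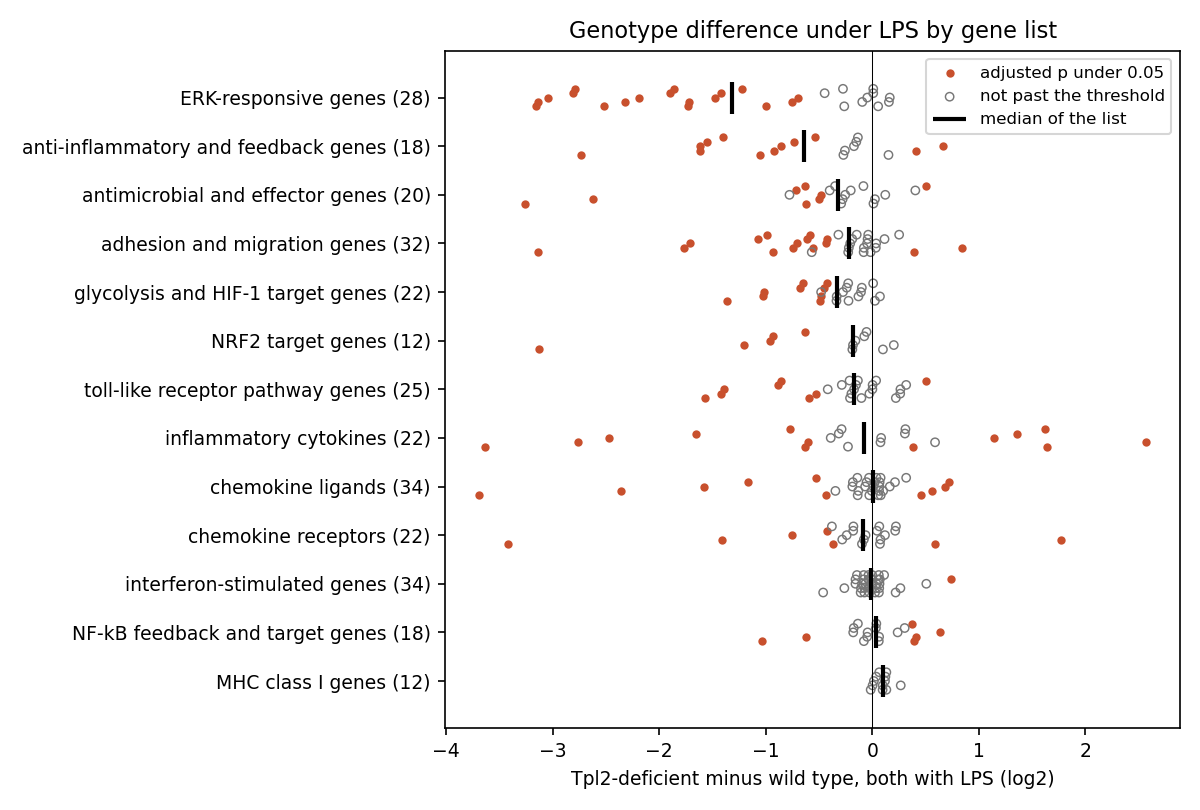
Log2 difference between Tpl2-deficient and wild-type macrophages, both with LPS (horizontal axis), for each measured member of 13 gene lists (n = 2 arrays per group); filled points have adjusted p under 0.05 and bars are list medians. ERK-responsive genes have the lowest of the medians drawn (-1.32), and the median of interferon-stimulated genes is -0.02 (0.02 with spike-in centring).

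The interaction asks whether the LPS response itself differs between the genotypes. For 1040 genes the change with LPS was more positive in Tpl2-deficient cells and for 523 more negative. Ccl7 rose by 5.79 ± 0.11 in wild type but by 2.38 ± 0.11 in Tpl2-deficient cells, a difference of -3.41 ± 0.16 (adjusted p = 2.1e-06), and Ccl2 rose by 5.65 ± 0.15 and 3.42 ± 0.15 (adjusted p = 0.00011). Ccr1 rose by 1.15 ± 0.14 in wild type and fell by 1.73 in Tpl2-deficient cells (difference -2.88 ± 0.20, adjusted p = 1.28e-05), while Cxcr4 fell 69.9-fold and 21.8-fold (adjusted p = 3.28e-05). Plaur and Egr1 rose in wild type (1.75 and 0.56) and fell in Tpl2-deficient cells (-0.81 and -1.98). Ifnb1 went from 5.67 to 7.51 in wild type and from 5.76 to 10.08 without Tpl2 (difference 2.49 ± 0.22), with both unstimulated levels under the array medians. Cxcl2, lower in Tpl2-deficient cells both with and without LPS, rose 26.9-fold in wild type and 24.4-fold without Tpl2 (difference -0.14 ± 0.14, adjusted p = 0.619).

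Of the chemokine ligands, 3 had a more negative and 1 a more positive response without Tpl2 (the same adjusted over the list alone; camera adjusted p = 0.142), and of the receptors 4 and 2 (5 and 2 adjusted over the list alone; camera adjusted p = 0.022, but adjusted p = 0.533 with an estimated correlation). Of the ERK-responsive genes, 16 were more negative and 0 more positive (16 and 0 adjusted over the list alone; adjusted p = 7.58e-19, and adjusted p = 0.0208 with an estimated correlation). Of the anti-inflammatory genes 7 were more negative (adjusted p = 5.98e-05, but adjusted p = 0.533 with an estimated correlation), led by Il10 (-2.82 ± 0.14). For interferon-stimulated genes 4 were more negative, among them Gbp2 (-0.91 ± 0.15) and Cmpk2 (-0.98 ± 0.19), and 1 more positive (adjusted p = 0.000582, but adjusted p = 0.719 with an estimated correlation). Under LPS 33 of the 34 did not pass and the list's median was -0.02 (0.02 with spike-in centring), so the interaction median of -0.24 mirrors the 0.27 at rest, where the calls of Gbp2 and Cmpk2 were lost on leaving out single arrays. Among the 1043 genes lower in LPS-treated Tpl2-deficient cells, 511 were genes that LPS raised in wild type, where independence gives 222, and 317 were genes that LPS lowered (323). Among the 1457 higher genes 862 were genes that LPS lowered (451) and 346 genes that LPS raised (310). Both comparisons use the wild-type LPS arrays, which links them by design. Simulated noise, independent between genes and equally wide in all groups, gave a correlation across genes of -0.07 (mean of 20 draws), against -0.24 observed. Noise shared between genes and the wider spread of the LPS-treated Tpl2-deficient arrays were not simulated. How much of the observed value the shared arrays account for is therefore not known. The number of interaction calls ranged from 756 to 2565 when any 1 of the 8 arrays was left out, with the lowest value without Tpl2-deficient unstimulated replicate 2 and the highest without LPS-treated Tpl2-deficient replicate 1. More negative responses made up 33.5% of the calls, 54.6% with spike-in centring and 43.8% with quantile normalization repeated.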

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

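The tests of weaker LPS stimulation, the spike-in difference and centring, fewer macrophages, sex, the lower share of LPS-raised genes and the chromosome of Map3k8 were chosen after the results they weigh were seen, and so was the requirement that other comparisons show fewer neighbouring genes. The neighbour test itself was set before its result was seen. The LPS response differed between the genotypes, by limma's interaction term at an adjusted p under 0.05, for 1040 genes with a more positive and 523 with a more negative response in Tpl2-deficient cells. Named genes with a more positive response were Arhgap22 (log2 difference of LPS responses 3.09), Socs2 (2.99), Efna2 (2.87), Plat (2.80), Cdc42ep3 (2.64), Gem (2.55), Tex15 (2.53), Ifnb1 (2.49), Cxcr4 (1.68), Il12b (1.01), Cxcr3 (0.79) and Cxcl11 (0.78). Named genes with a more negative response were Cd300lb (-4.46), Hcar2 (-4.16), Olr1 (-3.59), Il1a (-3.53), Dusp6 (-3.47), Ccl7 (-3.41), Zfp658 (-3.40), Ccr1 (-2.88), Il10 (-2.82), Fos (-2.74), Il1b (-2.66), Plaur (-2.55), Egr1 (-2.54), Ccl2 (-2.24), Ier2 (-2.24), Ccr3 (-1.40), Cxcl3 (-1.33), Ccr2 (-0.71) and Ccr1l1 (-0.66). The calls of Cxcl11, Cxcr3, Ccr1l1, Ccr2 and Il12b were each lost when Tpl2-deficient unstimulated replicate 1, among other single arrays, was left out, and the other 3 probe sets of Ccr2 showed no difference past the test.

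Data outside the gene comparisons also held signals. Among 10092 probe sets without a single gene symbol, 601 differed between the genotypes under LPS (318 higher and 283 lower in Tpl2-deficient cells), against 23 in unstimulated cells (9 higher and 14 lower). The 14 hybridisation spike-in probe sets, added in equal amounts to each sample by the array's design, read 0.17 higher (log2) in LPS-treated than unstimulated wild-type arrays and 0.27 higher in Tpl2-deficient arrays; the SD between the 2 unstimulated wild-type arrays was 0.124.

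The pattern weighed first is the lower level of ERK-responsive genes in LPS-treated Tpl2-deficient cells. Weaker LPS stimulation as a whole could lower interferon-stimulated and NF-kB genes as well. Their medians were -0.0161 and 0.036, which argues against a weaker response of these 2 lists. A weaker stimulus that they would not show stays open. Some members lie near the top of the arrays (Gbp2 14.4 in wild-type and 14.3 in Tpl2-deficient cells with LPS). Ifnb1 was higher and Tlr4 lower in the Tpl2-deficient cells. Spike-in centring moved every gene alike by 0.03, so the list's median of -1.28 after it (-1.32 before) decides nothing about scaling. A shift of whole arrays by scaling is argued against because the spike-ins themselves differed by -0.0327 ± 0.0567 (standard error between arrays). The macrophage markers had a median of -0.12 and a mean of -0.21 ± 0.14 (standard error across the marker genes, not between cultures). They show no large common drop, though camera at its preset correlation called the list lower. LPS itself changed markers such as Cebpa and Msr1 in wild type, so whether fewer macrophages were present cannot be told from them. The loss of Tpl2, which the design names, and a different timing of the LPS response stay open and were not tested.

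The next pattern is the set of 91 genes that differed in unstimulated cells. Different sex of the mice is argued against, since Xist and the Y-linked genes differed by at most 0.55. A candidate explanation is DNA inherited on the chromosome of the targeted allele: 9 of the 90 called genes other than Map3k8 lie on its chromosome, where 2.29 would be expected (exact hypergeometric test, one-sided, p = 0.000466), and 1 or 2 of as many leading genes of the other comparisons do. Fzd8, Colec12, Esco1, Abhd3 and Psma8 lie 15 to 46 measured genes from Map3k8. Further off, 131 to 381 genes away, lie Egr1 (which turns from higher to lower with LPS), Ppic, Tubb6 and Poli. The explanation may therefore cover a small part of the pattern only. At rest 0 of the 15 nearest measured neighbours of Map3k8 were called, which decides nothing, since only 0.50% of all genes were. Between the genotypes under LPS, 5 of those 15 were called, where 13.7% of all genes were. Whether DNA from another strain elsewhere in the genome plays a part cannot be told apart. Called genes formed 14 neighbour pairs against 4.41 in random sets (permutation p = 9e-05), and 84.6% of the 91 genes kept their sign under LPS. But as many leading genes formed 16 pairs in the wild-type LPS response, though 6, 8 and 7 in the Tpl2-deficient LPS response, the genotype comparison under LPS and the interaction. In 8 of the 14 pairs the signs were opposite, which decides nothing, since the prediction set no sign within pairs.

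The remaining pattern is that more genes fell than rose after LPS. Whether scaling made this share cannot be told apart: spike-in centring lowers every gene in LPS-treated wild-type arrays by 0.17, so the share could only grow, and it went from 59.2% to 77.2% of the calls. The SD of the spike-ins between the 2 unstimulated wild-type arrays was 0.124, close to that shift, and the share depends on the scaling. No other technical and no biological explanation was tested.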

How the results depend on the processing

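The spike-in centring and the crossed pairing were chosen after seeing the data, and the other alternatives were planned. Of 9548 alternative values for the 512 named results past the threshold, 9073 kept their direction and side of the threshold, 474 lost the threshold and 1 reversed. The differences of Ccl7, Ccl2, Cxcl3, Ccr1, Cxcr4, Il1b, Il10, Fos and Ifnb1 under LPS stayed past the threshold with their sign in each alternative that gave a value per gene. The runs with each probe set on its own and with a 2-fold minimum, and the other list tests, were not part of this check. With 2 arrays per group, leaving out an array leaves a lone sample assumed to vary like the other groups. The alternative for linear values was not run, since the values are already log2. For each changed result below the cause was not tested, except that a 2-fold minimum, fewer genes or fewer arrays change counts by construction.

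Testing each probe set on its own gave 7219 rises and 9460 falls with LPS in wild type, 5545 and 8083 in Tpl2-deficient cells, 1983 lower under LPS and 882 more negative interactions, since there are more probe sets than genes. A 2-fold minimum gave 994 and 2116, 1081 and 1550, 10 and 16, 190 and 272, and 232 and 229 higher and lower in the order of the report. Among genes above the median level 2106 rose with LPS in wild type. Spike-in centring gave 1896 rises in wild type, 1649 rises and 7361 falls in Tpl2-deficient cells, 63 higher and 31 lower at rest and 456 more positive interactions. Array weights gave 142 higher and 389 lower at rest and 852 higher under LPS. Only the 4 arrays compared gave 16 and 32 at rest, and the variance trend gave 99 lower at rest. With the replicate number as a paired replicate block the counts were 3783 and 5590, 2869 and 4640, 28 and 57, 1394 and 994, and 955 and 499. Deviations of same-numbered arrays correlated between -0.12 and 0.10 across groups, so the numbers show no pairing. A crossed pairing of the Tpl2-deficient arrays gave 2761 rises and 4517 falls with LPS.

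The number of lists past the test was 13, 11, 5, 9 and 11 in the order of the report. With an estimated correlation it was 0, 0, 0, 1 and 1, the ERK-responsive list remaining. With fry it was 21 and 21 for LPS, 0 at rest and 5 for the interaction. At rest it was 8 with the mean of all probe sets, 2 with quantile normalization repeated, 2 among genes above the median level and 8 with spike-in centring. The chemokine ligands at rest (adjusted p = 0.999) turned sign but stayed far from the threshold with the mean of all probe sets (0.837), without _x_at and _s_at probe sets (0.668), with quantile normalization (0.679), with fry (0.879) and with spike-in centring (0.912). Under LPS the ligands passed with fry (0.0456), and in the interaction they passed among genes above the median level (0.0118). The receptors' interaction (0.022) was lost with the mean of all probe sets (0.0516), among genes above the median level (0.514), with an estimated correlation (0.533) and with fry (0.0678). The ratio of the LPS responses among genes called in wild type (0.725) became 0.791 among genes above the median level and 0.876 with spike-in centring, and among genes called in Tpl2-deficient cells (0.929) 0.990 with spike-in centring.

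Single genes reversed where probe sets disagree. With the mean of all probe sets the change with LPS in wild type became -0.389 for Meis1 (0.34) and -0.655 for Ccr2 (0.29, not past), and Cxcl1 at rest became -0.570 (0.31, not past). Without _x_at and _s_at probe sets Cxcl1 became -1.72 at rest and 1.22 in the interaction (-0.45, not past), and both of these new values passed.

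Leaving out 1 array in turn gave 8 to 32 higher and 15 to 79 lower genes at rest, 713 to 1791 higher and 630 to 1499 lower under LPS, and 406 to 1691 more positive and 314 to 921 more negative interactions. The lowest values came without wild-type unstimulated replicate 2 at rest, without a wild-type LPS array under LPS, and without Tpl2-deficient unstimulated replicate 2 or wild-type LPS replicate 2 for the interaction; the highest came without an LPS-treated Tpl2-deficient array, the group with the widest spread. Among genes called in both, 0 changed sign. Lists past the test numbered 2 to 9 at rest and 5 to 12 for the interaction. Adjusted p ranged from 0.419 to 0.983 for the ligands and 6.95e-07 to 0.555 for the stromal markers at rest (upward without Tpl2-deficient unstimulated replicate 2, the lowest value, and downward at 0.0149 without replicate 1), and from 0.0337 to 0.525 for the ligands and 0.0125 to 0.0891 for the receptors in the interaction. The ratios ranged from 0.664 to 0.780 and from 0.899 to 1.01.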

Other observations

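Other gene lists were read in the comparison of LPS-treated Tpl2-deficient and wild-type macrophages. Of 22 glycolysis and HIF-1 target genes, 9 were lower and 0 higher in Tpl2-deficient cells (13 and 0 adjusted over the list alone), with the glucose transporter Slc2a1 2.57-fold and the hypoxia-induced Ankrd37 at least 2.04-fold lower (camera adjusted p = 6.68e-08, but adjusted p = 0.321 with an estimated correlation; 0.0171 with fry). Of 12 NRF2 target genes, 5 were lower and 0 higher, with the haem-degrading Hmox1 8.72-fold lower (8.14 against 11.26), the cystine transporter Slc7a11 2.30-fold lower and the glutathione reductase Gsr 1.95-fold lower (adjusted p = 5.07e-05, but adjusted p = 0.321 with an estimated correlation and 0.00312 with fry). Of 13 LXR target genes, 5 were lower and 2 higher (median -0.31, mean -0.11; adjusted p = 0.0201, but adjusted p = 0.321 with an estimated correlation and 0.215 with fry). Mylip, which promotes degradation of the LDL receptor, went against that list: LPS lowered it by 1.90 ± 0.10 in wild type and raised it by 0.41 in Tpl2-deficient cells, a difference under LPS of 2.45 ± 0.10. Ciita, the only MHC class II list member of 12 to differ, was 3.47-fold higher (9.27 against 7.47), and 0 of 12 MHC class I genes differed (camera adjusted p = 0.470 and 0.453). Cholesterol synthesis genes were 2 higher and 2 lower of 20 (0.797), alternative activation genes 2 higher and 3 lower of 19 (0.445), and cell cycle genes 1 higher and 0 lower of 35 (0.575), so these 5 lists did not pass.

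Kinases of the Tpl2 pathway list moved both ways under LPS, 4 higher and 4 lower of 17 (camera adjusted p = 0.746). Mapk14, the p38 alpha kinase, was 2.49-fold lower and Ikbkb, a kinase of the NF-kB pathway, 2.00-fold higher in Tpl2-deficient cells. Of 18 listed neighbours of Map3k8, 4 were higher and 1 lower under LPS, with Zfp438 at 1.10 ± 0.13, and at rest only Fzd8 differed (0.85 ± 0.14). The transcription factor gene Zeb1 in that list rose with LPS by 3.27 ± 0.13 in wild type and 4.26 ± 0.13 in Tpl2-deficient cells (interaction adjusted p = 0.006). Among marker lists under LPS, osteoclast markers were 1 higher and 4 lower of 10, with Acp5 2.04-fold higher and Dcstamp 2.29-fold lower. Stromal markers were 1 and 1 of 13, mast cell markers 1 and 0 of 10, dendritic cell markers 0 and 1 of 12, and erythroid markers 0 and 1 of 9. Those of T and NK cells, of B cells and of progenitors showed 0 calls in lists of 12, 12 and 8. Of 4 sex-linked genes 1 was higher (Eif2s3y, 0.45 ± 0.13, lost without either LPS-treated wild-type array), and of 9 reference genes 1 was lower (Tubb5, -0.84 ± 0.12), while Actb (-0.02 ± 0.10) and Hprt (0.11 ± 0.10) did not pass.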
